A study of Drosophila melanogaster with 9 samples.

How the data were processed

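The data are RNA sequencing measurements of ovarian follicles from adult Drosophila melanogaster females. Per the labels' protocols, follicles were dissected by stage at room temperature, 100 follicles made up each sample, and libraries were built from poly(A)-selected RNA with the TruSeq v2 kit. There are 9 libraries in 3 groups of 3: wild-type stage 8, wild-type stage 10, and stage 10 from females carrying a temperature-sensitive EcR mutation (EcRts). Wild-type females were kept at 25 °C, and 2 days after eclosion the EcR mutants were moved to a temperature that inactivates the receptor, per the labels' protocols. That temperature, the EcR alleles, and whether the samples of a group came from separate animals or days are not given in the sources used here. The labels name the strain Oregon R for all 9 samples and an age of 6 to 14 days, while the growth protocol states a lower minimum age.

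The submitters' processing notes name CASAVA 1.8.2, Bowtie2 2.0.6, TopHat2 2.0.7, Cufflinks 2.02 and the genome build dm3. The deposited values are gene-level FPKM (fragments scaled by transcript length and by library size) from Cufflinks, with a confidence interval and a status for each gene. The annotation release, the strand setting and the read counts are not given in the sources used here. No further normalization between libraries is stated in the labels.

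Each file listed 15602 genes, and the identifiers were the same in all 9 libraries. A current reference annotation served only for gene names and gene types, and 14926 identifiers matched it. 5 symbols that a spreadsheet had turned into dates were restored from the gene identifiers. Gene positions are printed from 1 in dm3. 21 genes whose estimate had failed in a library, and which were listed there at 0, were left out of the tests, 16 of them noncoding genes on unplaced or heterochromatic scaffolds at up to 15935.5 FPKM in another library. Sums of FPKM, except that over protein-coding genes, include them as listed. This rule was added after the files were seen. No 2 libraries held identical values (0 identical pairs).

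The depth behind the values was derived from the deposited confidence limits of genes with status OK. The distance from a value to its upper limit was taken as a fixed multiple of the error of a fragment count. Implied counts under 50 fell within 0.02 of a whole number for 56.6% to 60.6% of such genes in a library, so counts were not recovered whole and no count-based test was run. The implied totals are 17.5 to 21.7 M fragments for the wild-type libraries and 27.2 to 33.3 M for the EcRts libraries.

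Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, 8340 genes in all. Values were transformed to log2(FPKM + 1), which makes changes of genes near 1 FPKM look smaller than they are. A linear model with 1 mean per group was fitted to all 9 libraries in limma 3.58.1 (R 4.3.3) with an intensity trend in the variance prior and 6 residual degrees of freedom. The 3 comparisons are wild-type stage 10 against wild-type stage 8, EcRts stage 10 against wild-type stage 10, and EcRts stage 10 against wild-type stage 8. Adjusted p-values are limma p-values adjusted by Benjamini-Hochberg within a comparison, and a gene is said to have risen, fallen or differed when its adjusted p was under 0.05. The p-values measure the spread between these samples. Shares of the summed FPKM were compared with exact two-sided permutation tests. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

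28 gene lists were written from general knowledge of fly biology. They cover vitelline membrane, chorion, yolk and lipoprotein uptake, lipid synthesis, lipolysis and beta-oxidation, nuclear-encoded oxidative phosphorylation, the TCA cycle, glycolysis, glycogen and trehalose, ecdysone response, ecdysteroid synthesis, DNA replication and endocycle, mitotic cycle, maternal patterning and germline, follicle cell patterning, actin and nurse cell dumping, muscle, fat body, hemocyte, germarium, neuron, heat shock, immune peptides, apoptosis and autophagy, insulin and TOR, xenobiotic and oxidative stress, ribosomal proteins, and the proteasome. Hemocyte and neuron had fewer than 3 tested members and were not analysed further. The proteasome list was taken by symbol pattern and includes Prosap, which is not a subunit. Of the list members, 591 were matched to the files and 1 was not. The remaining 26 lists were compared with all other tested genes by camera in limma with a preset correlation of 0.01 between genes, adjusted over the 26 lists. Each list's members were also counted as adjusted over the list alone.

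Named genes follow a rule: the 10 largest rises and 10 largest falls of the first 2 comparisons among genes with adjusted p under 0.05, groups that do not overlap, and a mean of at least 5 FPKM in the higher group, without small RNAs (by a symbol pattern that does not match mitochondrial transfer RNAs) and pseudogenes; always EcR and usp; and, for each list with a camera call or at least 3 called members, up to 4 members with the smallest adjusted p. The symbol pattern leaves out every gene whose symbol starts with CR, so other noncoding RNA genes with such symbols were not ranked either. Of the list members that meet the rule, those whose call held under the alternatives below were preferred. That preference was not part of the rule and was applied after the results were seen. Genes named outside this rule are marked as such where they appear. The groups, comparisons, tests, lists, this rule and the alternatives below were chosen before the data were examined, except where said otherwise.

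Alternatives were a pseudocount of 0.1 or 5; no filter, or a mean of at least 5 FPKM; median-of-ratios scaling; quantile normalization; scaling to the sum outside the eggshell and yolk lists; fits to only the 2 groups compared; no trend; robust variance; array weights; only genes with status OK in all libraries; a block for the replicate number; leaving out each library in turn; a correlation estimated per list; fry in place of camera; a change of at least 2-fold; and only genes called in the stage comparison. Scaling to the sum over protein-coding genes was added after seeing the data. The scalings referred to in the results are median-of-ratios, quantile, without eggshell and yolk genes, and protein-coding.

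The test was tried on simulated data in which 100 of 8340 genes were changed by each fold. In the stage comparison 74% of changes of 1.5-fold and 91% of changes of 2-fold were recovered, with 5 false calls among 8140 unchanged genes. The comparison of EcRts with wild-type stage 10 recovered 77% and 88%, with 6 false calls. The simulated noise was normal, independent between genes and without a shift common to a library. The rate of false calls therefore need not hold for the real data. Isoforms, splicing and reads were not analysed here. Copies of near-identical genes (Hsp70, histones, 5S rRNA, actins) share reads, so a single copy's value is less certain than that of its family.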

Results

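Poly(A) RNA was measured in staged ovarian follicles of Drosophila melanogaster. A follicle, or egg chamber, holds the oocyte and its sister nurse cells inside an epithelium of somatic follicle cells that builds the eggshell. At stage 8 the oocyte has begun to take up yolk, and at stage 10 yolk uptake is well advanced, the eggshell is being laid down and the nurse cells are close to emptying their contents into the oocyte. The 3 groups are wild-type stage 8, wild-type stage 10 and stage 10 from EcRts females, with 3 libraries of 100 follicles in each. EcR encodes the receptor for the steroid hormone ecdysone, which binds DNA together with its partner usp. The EcRts females were also kept at another temperature than the wild type, so genotype and temperature differ together. Implied sequencing depth, given below, differed along with them, being higher in every EcRts library than in any wild-type library. Values are mean FPKM ± SD over the 3 libraries of a group unless stated otherwise, and changes are differences of mean log2(FPKM + 1).

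The confidence limits of the deposited values imply 18.6 to 21.7 M fragments in the stage 8 libraries, 17.5 to 21.3 M in the wild-type stage 10 libraries and 27.2 to 33.3 M in the EcRts libraries. Between 7924 and 8202 genes reached 1 FPKM in a library. Across all 15602 listed genes, which are not independent replicates, log2(FPKM + 1) of libraries of the same group correlated at 0.973 to 0.982. Libraries of different groups correlated at 0.946 to 0.966. The first principal component (35.0% of the variance) separated stage 8 from both stage 10 groups, and the second (23.6%) separated EcRts from both wild-type groups.

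Eggshell transcripts made up 1.76% ± 0.528 of the summed FPKM at stage 8, 6.52% ± 0.699 in wild-type stage 10 and 4.76% ± 0.417 in EcRts. Ribosomal protein transcripts took 30.8% ± 1.07, 26.1% ± 0.941 and 20.7% ± 0.824 in the same order. Heat shock transcripts held 0.589% ± 0.154, 1.01% ± 0.0818 and 0.368% ± 0.0143. The 3 yolk protein genes held 0.949% ± 0.158, 1.21% ± 0.0999 and 1.18% ± 0.0721. Messenger RNAs of the mitochondrial genome held 1.11% ± 0.183, 2.36% ± 1.16 and 0.863% ± 0.147, and the wide spread at wild-type stage 10 came from replicate 3, at 3.70%. The 10 most abundant genes of a library held 13.8% ± 0.719, 13.0% ± 1.15 and 18.6% ± 1.34. A further 94 noncoding RNA genes on unplaced or heterochromatic scaffolds held 20.2% ± 2.34, 10.0% ± 0.861 and 29.0% ± 1.85. Of these 58 have no current symbol and 6 have that of a ribosomal RNA or its pseudogene. The share left for all other genes therefore differed between groups. In 16 of these genes the estimate had failed in a library, where they are listed at 0, and without the genes with failed estimates the shares were 13.2% ± 1.61, 6.25% ± 0.43 and 25.6% ± 2.56. Exact two-sided permutation tests of 3 against 3 libraries cannot go below p = 0.1, and 17 of the 21 comparisons of shares reached that value (adjusted p = 0.124).

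**Figure D1:**
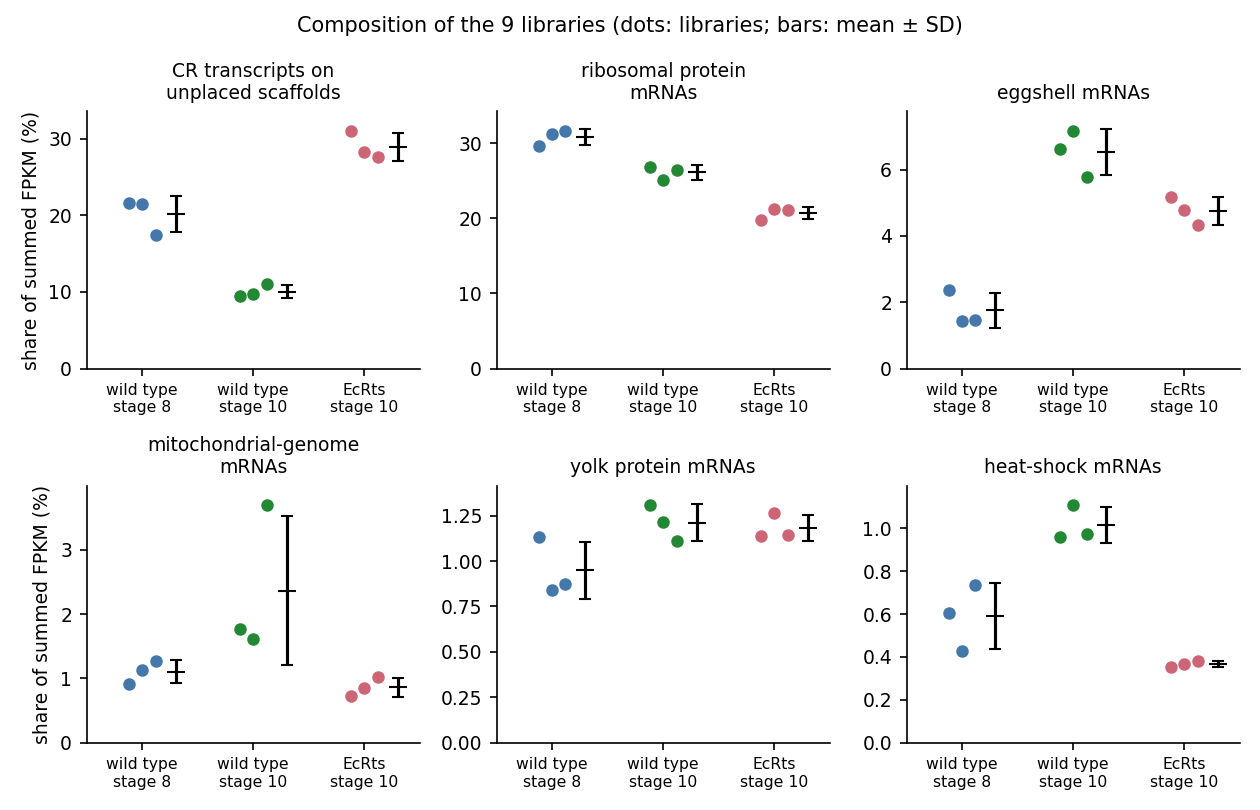
Share of the summed FPKM (percent, y axis) taken by 6 groups of transcripts in wild-type stage 8, wild-type stage 10 and EcRts stage 10 follicles; dots are the 3 libraries of a group and bars are means ± SD. The mean eggshell share was 1.76% at stage 8, 6.52% at wild-type stage 10 and 4.76% in EcRts, and transcripts of unplaced scaffolds took 20.2%, 10.0% and 29.0%.

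The comparison of wild-type stage 10 with stage 8 asks which transcripts change as a follicle passes through the middle of oogenesis. With the values as deposited most genes for the eggshell, the cell cycle, the proteasome and nurse cell dumping were more abundant at stage 10, and most ribosomal protein genes and several follicle cell patterning genes were less abundant. Of the 8340 tested genes 5682 passed the test, 4105 higher and 1577 lower at stage 10, and 598 of the former and 194 of the latter changed at least 2-fold. Higher genes were 72.2% of the calls with the values as deposited, 49.3% with median-of-ratios scaling, 50.9% with quantile normalization, 86.1% without eggshell and yolk genes and 66.2% with protein-coding scaling. The median change of all tested genes was 0.20, and it was −0.01, −0.01, 0.42 and 0.14 under these scalings in the same order. The camera results given below compare a list with the other genes and are relative to that shift.

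Among the largest rises, Fcp3C (FBgn0000644, chromosome X, 3067409 to 3068507), which codes for a follicle cell protein, rose from 17.9 ± 8.07 to 458 ± 83.5 FPKM, a log2 change of 4.70 (adjusted p = 1.45e-05). CG14187 (FBgn0036938, chromosome 3L, 20105365 to 20105947) rose from 14.4 ± 5.02 to 358 ± 47.5 (4.59, adjusted p = 5.61e-06). Obp19c, an odorant-binding protein gene, rose from 32.1 ± 7.54 to 493 ± 24.7, and CG10407, now called Jhbp5, from 33.8 ± 6.21 to 502 ± 55.2. CG9990, now called snu, an ABC transporter gene, rose from 1.69 ± 0.613 to 38.6 ± 4.00. The uncharacterised genes CG42821, CG31661, CG42822, CG34166 and CG14309 rose by 3.91 to 4.46 on the log2 scale. Among the largest falls, CG13636 (FBgn0039232, chromosome 3R, 20659676 to 20666217), now called sosie and needed for an ordered follicle epithelium, fell from 30.5 ± 6.11 to 2.08 ± 0.823, a log2 change of −3.37 (adjusted p = 2.5e-05). The Notch target HLHmbeta fell from 17.8 ± 4.58 to 3.46 ± 0.253 and its relative Her from 7.55 ± 2.31 to 1.15 ± 0.363. CG6490, now called plum, fell from 12.4 ± 1.59 to 3.12 ± 0.158 and CG15529 from 12.3 ± 1.44 to 3.07 ± 0.377. CG30409, CG32368 and CG14798, which the current annotation lists as RNA genes, had log2 changes of −1.75 to −1.94. Acp98AB had 6.89 ± 4.96 FPKM at stage 8 and was listed at 0 in every stage 10 library. CG17922 also met the rule (adjusted p = 0.025), but its call was lost without wild-type stage 10 replicate 1 (adjusted p = 0.0566), replicate 2 (0.0579) or replicate 3 (0.0594) and with a pseudocount of 5 (0.0688), with a range of 0.00801 to 0.0688 over the alternatives.

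Most eggshell genes rose. All 11 tested chorion genes, which build the outer eggshell, rose with the values as deposited, and 10 or 11 rose under each scaling, with a median change of 2.94 (camera adjusted p = 0.0152, and 0.594 with an estimated correlation). The camera call was lost without eggshell and yolk genes (adjusted p = 0.121; 3.5e-04 to 0.594 over the alternatives with camera, and 1.1e-05 with fry). Cp7Fb rose from 33.6 ± 11.8 to 448 ± 29.1 FPKM and Cp7Fc from 93.9 ± 31.1 to 1041 ± 76.2, and the abundant Cp36 and Cp38 from 478 ± 213 to 3206 ± 414 and from 666 ± 272 to 4624 ± 446. Cp38 (FBgn0000360) lies on chromosome X at 8375870 to 8377344. Of the 13 tested genes of the vitelline membrane list, 10 rose and 3 fell (median 1.51, camera adjusted p = 0.46). That list was written for the inner eggshell and its crosslinking factors, and whether every member belongs only there was not tested. Vm26Ac rose from 30.1 ± 12.6 to 272 ± 13.5, Vm32E (FBgn0014076, chromosome 2L, 11171229 to 11171665) from 577 ± 257 to 4324 ± 294, and dec from 381 ± 193 to 2159 ± 208. The genes that fell were clos, from 150.01 ± 14.2 to 77.6 ± 4.26, and, named after their values were seen, fs(1)N and fs(1)M3, which changed by −0.51 and −0.50. Of 8 yolk and lipoprotein uptake genes 4 rose and 3 fell (median 0.10, camera lower, adjusted p = 0.323), a balance that turned under median-of-ratios scaling to 1 rise and 4 falls. The yolk receptor gene yl fell from 515 ± 25.6 to 360.3 ± 30.6 and the lipoprotein receptor gene LpR1 from 12.5 ± 0.585 to 7.88 ± 0.259. For these 3 lists the counts adjusted over the list alone were the same.

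**Figure D2:**
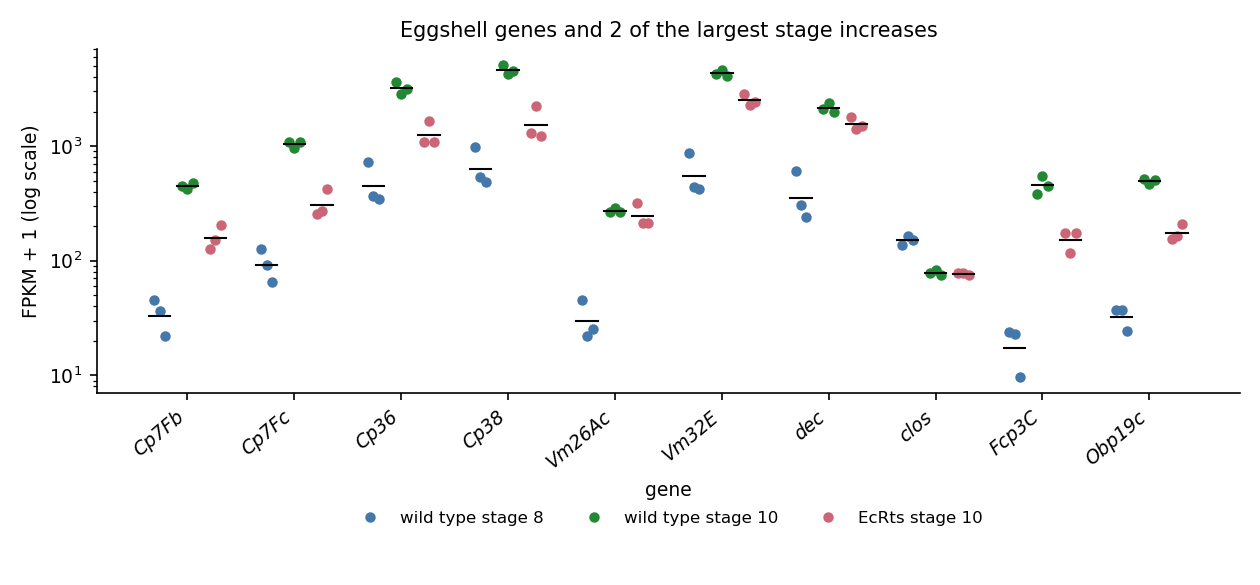
FPKM + 1 (y axis, log scale) of 10 eggshell and follicle cell genes in the 3 groups; dots are libraries and bars are the means of log2(FPKM + 1) of a group. The chorion genes and Vm32E lie higher at wild-type stage 10 than at stage 8, with EcRts between the 2 wild-type groups, while clos fell from 150.01 to 77.6 FPKM.

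Most cell cycle genes rose. Of 23 DNA replication and endocycle genes 21 rose and 1 fell (median 0.69, camera adjusted p = 1.22e-04, and 0.594 with an estimated correlation). CycE rose from 28.7 ± 1.18 to 71.1 ± 4.30 FPKM, Orc2, of the origin recognition complex, from 8.75 ± 0.632 to 25.4 ± 0.91, Mcm3, of the replicative helicase, from 26.4 ± 1.39 to 49.4 ± 1.05, and RnrL, which makes deoxynucleotides, from 66.9 ± 5.16 to 159.7 ± 2.80. Of 17 mitotic cycle genes 16 rose, or 17 when adjusted over the list alone (median 0.81, camera adjusted p = 1.22e-04, and 0.594 with an estimated correlation). The securin gene pim rose from 16.5 ± 2.16 to 93.3 ± 6.28, mad2, of the spindle checkpoint, from 36.7 ± 1.42 to 108 ± 8.25, fzy from 23.2 ± 0.35 to 41.5 ± 0.984, and the meiotic Cdc25 gene twe from 16.2 ± 0.898 to 46.0 ± 1.29. Among 14 genes for actin and nurse cell dumping 13 rose and 1 fell (median 0.45, camera adjusted p = 0.0141, and 0.594 with an estimated correlation). The villin-like gene qua rose from 23.9 ± 1.12 to 41.4 ± 1.14, the fascin gene sn from 46.5 ± 1.82 to 66.9 ± 2.42, and Act5C from 1161 ± 64.2 to 1801 ± 43.9. Directions of these 3 lists held under every scaling, and the counts of the first and last were the same adjusted over the list alone.

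Maternal and epithelial patterning genes moved in both directions. Among 21 maternal patterning and germline genes 11 rose and 7 fell (8 adjusted over the list alone; median 0.10, camera lower, adjusted p = 0.388), which turned under median-of-ratios scaling to 7 rises and 11 falls. The posterior determinant nos rose from 87.2 ± 2.39 to 168 ± 13.2 FPKM and exu, a factor in bicoid mRNA localization, from 212 ± 18.8 to 407 ± 20.7, while the oocyte RNA-binding protein gene orb fell from 296 ± 19.0 to 134 ± 9.82. Of 18 follicle cell patterning genes 4 rose and 10 fell (median −0.29, camera adjusted p = 0.00976, and 0.594 with an estimated correlation), and the counts were the same adjusted over the list alone. N, the Notch receptor gene, fell from 17.1 ± 0.757 to 9.38 ± 0.284, eya, active in the early epithelium, from 12.1 ± 1.69 to 5.61 ± 0.466, and peb, a zinc-finger gene, by 0.76 on the log2 scale, while the cell adhesion gene Fas3 rose from 6.63 ± 0.23 to 18.9 ± 1.48. Among 4 germarium genes 1 rose and 2 fell (median −0.24, mean 0.12, camera lower, adjusted p = 0.205, and 0.0144 with no filter, in a range of 0.0144 to 0.699 over the alternatives), and the differentiation gene bam rose from 4.89 ± 0.318 to 15.3 ± 1.31. With scaling outside eggshell and yolk genes the germarium list had 1 rise and 1 fall.

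Genes of ecdysone response and synthesis also split. Of 20 ecdysone response genes 8 rose and 5 fell (median 0.08, camera lower, adjusted p = 0.46), turning to 4 rises and 8 falls under median-of-ratios scaling. Eip74EF, an early ecdysone-induced transcription factor gene, rose from 2.83 ± 0.253 to 11.2 ± 0.823 FPKM, and Cyp18a1, which inactivates the hormone, from 7.32 ± 1.56 to 16.7 ± 0.688, while the early gene Eip75B fell from 25.1 ± 2.64 to 14.2 ± 0.857. EcR (FBgn0000546, chromosome 2R, 1975378 to 2056592) had 19.4 ± 0.446 at stage 8 and 21.0 ± 1.36 at stage 10, a change of 0.11 that did not pass (adjusted p = 0.117), with a range of 0.00115 to 0.605 over the alternatives. It fell by 0.17 with quantile normalization (adjusted p = 0.00916) and rose by 0.32 without eggshell and yolk genes (adjusted p = 0.00115). Its partner usp rose from 41.5 ± 0.448 to 50.4 ± 3.97 (0.27, adjusted p = 0.00463), a call lost with median-of-ratios scaling (adjusted p = 0.529) and quantile normalization (adjusted p = 0.462; 1.15e-04 to 0.529 over the alternatives). Of 13 ecdysteroid synthesis genes 3 rose and 5 fell (median −0.30, camera adjusted p = 0.092), counts that turned to 6 rises and 4 falls without eggshell and yolk genes. Without stage 8 replicate 2 this list passed camera (adjusted p = 0.0413; 0.0413 to 0.721 over the alternatives). The synthesis gene sad fell from 10.4 ± 0.145 to 4.94 ± 0.495 and Start1, a cholesterol transfer gene, rose from 21.9 ± 0.174 to 31.2 ± 1.30. Counts of both lists were the same adjusted over the list alone.

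Genes of energy metabolism moved in both directions. Of 12 glycolysis genes 9 rose and 1 fell (median 0.50, camera adjusted p = 0.092), with Gapdh2 from 650.02 ± 24.9 to 1178 ± 37.8 FPKM and Pglym78 from 189 ± 11.5 to 322 ± 10.5. Of 11 glycogen and trehalose genes 9 rose and 1 fell (median 0.56, camera adjusted p = 0.14), among them the trehalase gene Treh, from 49.5 ± 0.323 to 74.5 ± 4.80, and the kinase gene sgg, from 41.2 ± 1.04 to 61.2 ± 2.03. Of 18 lipolysis and beta-oxidation genes 13 rose and 1 fell (median 0.35, camera adjusted p = 0.156), with the thiolase gene yip2 rising from 79.4 ± 9.07 to 153 ± 5.52. In the lipid synthesis list 14 of 25 genes rose and 4 fell (median 0.15, camera adjusted p = 0.877), turning to 6 rises and 8 falls under median-of-ratios scaling, and the lipid droplet gene Lsd-2 rose from 217 ± 12.2 to 375 ± 31.9. Of 42 nuclear genes of oxidative phosphorylation 12 fell and 2 rose (9 and 1 adjusted over the list alone; median −0.07), but 21 rose and 0 fell without eggshell and yolk genes. Their camera adjusted p was 4.73e-04, and 0.699 with an estimated correlation. That call was lost without eggshell and yolk genes (adjusted p = 0.374; 1.3e-06 to 0.699 over the alternatives). Of 15 TCA cycle genes 2 rose and 6 fell (median −0.05), which turned to 8 rises and 4 falls without eggshell and yolk genes (camera lower, adjusted p = 0.0218, and 0.699 with an estimated correlation). The call for this list was lost without eggshell and yolk genes (adjusted p = 0.153) and with no filter (0.0513), with a range of 0.00234 to 0.699 over the alternatives. With no filter the glycolysis (camera adjusted p = 0.00803), glycogen and trehalose (0.0144) and lipolysis and beta-oxidation lists (0.00992) passed, each the lowest of a range up to 0.699 over the alternatives with camera. With fry, which makes no comparison with other genes, these 3 lists had adjusted p = 8.14e-05, 1.22e-04 and 1.93e-04. The citrate synthase gene kdn fell from 171 ± 16.0 to 107 ± 11.3 and Idh rose from 189 ± 2.13 to 249.7 ± 13.5. Counts of the other lists in this group were the same adjusted over the list alone.

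With the values as deposited most ribosomal protein genes fell and proteasome genes rose. Of 88 ribosomal protein genes 84 fell and 0 rose (median −0.43, camera adjusted p = 1.27e-30, and 0.594 with an estimated correlation), though with quantile normalization 10 rose and 34 fell and the camera call was lost (adjusted p = 0.0517; 5.31e-34 to 0.594 over the alternatives). RpL22 fell from 1961 ± 90.5 to 1071 ± 83.8 FPKM and RpL4 from 2612 ± 56.9 to 1575 ± 109. All 30 proteasome genes rose (median 0.57, camera adjusted p = 5.83e-05, and 0.699 with an estimated correlation), with Prosalpha1 from 123 ± 14.5 to 220.1 ± 10.3 and Rpn12 from 111 ± 15.4 to 202 ± 1.18. Under the scalings 26 to 30 of them rose. Both counts were the same adjusted over the list alone.

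Stress, death and growth pathway lists did not pass camera with the values as deposited. Of 18 heat shock genes 10 rose, or 5 when adjusted over the list alone (median 0.56, camera adjusted p = 0.323, and 0.0367 with quantile normalization, in a range of 0.0367 to 0.857 over the alternatives with camera, and 0.0183 with fry). Under the scalings 5 to 15 rose. Without stage 8 replicate 2, whose Hsp70 copies summed to 624 FPKM against 1080 and 1173 in the other stage 8 libraries, the median was 0.27, with 10 rising and 1 falling, and 5 rose without any 1 of the wild-type stage 10 libraries. Hsp26 rose from 1113 ± 289.6 to 2520.04 ± 194 FPKM, Hsp27 from 415 ± 90.1 to 883 ± 95.2, and stv, a co-chaperone gene, from 11.4 ± 0.866 to 26.7 ± 2.60. Of 19 apoptosis and autophagy genes 11 rose and 1 fell (median 0.23, camera adjusted p = 0.388), with 5 rises and 5 falls under quantile normalization. The initiator caspase gene Nc (Dronc) rose from 21.2 ± 0.688 to 43.7 ± 1.38 and the effector caspase gene Ice (Drice) from 24.4 ± 0.956 to 44.7 ± 1.32. In the insulin and TOR list 4 of 16 genes rose and 6 fell (median −0.03, mean 0.04, camera lower, adjusted p = 0.206), turning to 7 rises and 2 falls without eggshell and yolk genes, and Thor, the 4E-BP gene, fell from 157 ± 20.2 to 71.8 ± 7.18. Of 19 xenobiotic and oxidative stress genes 10 rose and 2 fell (median 0.21, camera adjusted p = 0.681), which became 6 and 6 under median-of-ratios scaling, and GstD1 rose from 409 ± 11.8 to 739 ± 51.0. Of 7 immune peptide genes 2 rose (median 0.36, camera lower, adjusted p = 0.877). Markers of other tissues were low or mixed, with 3 of 10 muscle genes rising and 1 falling (median 0.10, −0.02 with median-of-ratios scaling, camera lower, adjusted p = 0.877) and 3 of 5 fat body genes rising and 1 falling (median 0.32, camera adjusted p = 0.915). Apart from heat shock, the counts were the same adjusted over the list alone.

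EcRts stage 10 follicles were compared with wild-type stage 10 follicles to ask which transcripts differ when EcR is impaired, with temperature differing as well. All 18 heat shock genes were lower in EcRts with the values as deposited, the Hsp70 copies, Hsp68 and Hsp67Bc by the most. With the values as deposited 8 of 11 chorion genes and 16 of 23 DNA replication genes (5 to 22 under the scalings) were lower too, and 1 of 13 genes of the vitelline membrane list. In all, 3654 of the 8340 genes passed the test, 828 higher and 2826 lower in EcRts, and 229 of the former and 246 of the latter differed at least 2-fold. Higher genes were 22.7% of the calls with the values as deposited, 51.1% with median-of-ratios scaling, 47.8% with quantile normalization, 8.09% without eggshell and yolk genes and 68.1% with protein-coding scaling. The median change of all genes was −0.12, and 0.00, −0.01, −0.29 and 0.07 under these scalings in the same order.

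The mRNA level of EcR itself was 20.6 ± 0.67 FPKM in EcRts and 21.0 ± 1.36 in wild-type stage 10 (−0.02, adjusted p = 0.731), and without eggshell and yolk genes the change was −0.20 (adjusted p = 0.0157; 0.0157 to 0.999 over the alternatives). A temperature-sensitive protein can lose function without a change in its mRNA, so this value is no check of the genotype labels. Transcripts of usp were at 58.1 ± 2.88 against 50.4 ± 3.97 (0.20, adjusted p = 0.0291). That call was lost without wild-type stage 10 replicate 1 (adjusted p = 0.0644) or replicate 3 (0.0711), without EcRts replicate 1 (0.0812) or replicate 2 (0.0922), with only the 2 groups compared (0.0546), and without eggshell and yolk genes (0.796), with a range of 0.00217 to 0.796 over the alternatives.

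Every one of the 18 heat shock genes was lower in EcRts, with a median change of −4.15 (camera adjusted p = 3.88e-10, and 0.802 with an estimated correlation), and 16 to 18 were lower under the scalings. The 6 Hsp70 copies had a median of −6.66 and the 12 other members one of −1.34, with −0.17 as the smallest fall. Adjusted over the list alone the count was 18. Hsp70Bb (FBgn0013278, chromosome 3R, 8331515 to 8334105) was at 203 ± 6.46 FPKM in wild-type stage 10 and 0.731 ± 0.108 in EcRts, a log2 change of −6.88 (adjusted p = 1.32e-06). Hsp70Bc, Hsp70Bbb and Hsp70Ba had log2 changes of −6.79, −6.71 and −6.61, and the copies Hsp70Ab and Hsp70Aa of −5.62 and −5.61. The 6 Hsp70 copies share most of their sequence, and their summed FPKM was 1274 to 1399 in wild-type stage 10 libraries and 11.4 to 15.0 in EcRts libraries. Hsp68 (FBgn0001230, chromosome 3R, 19880802 to 19883029) went from 336 ± 27.6 to 2.38 ± 0.541, Hsp67Bc from 41.3 ± 3.87 to 0.249 ± 0.042 and stv from 26.7 ± 2.60 to 1.43 ± 0.256. The alphagamma-element:CR32865, a noncoding RNA that lies between Hsp70 copies and shares their promoter sequence, went from 102 ± 13.2 to 0.352 ± 0.135. Wild-type stage 8 follicles also had 140.0 ± 43.5 FPKM of Hsp70Bb and 224 ± 80.5 of Hsp68, so wild-type follicles of both stages carried these transcripts.

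**Figure D3:**
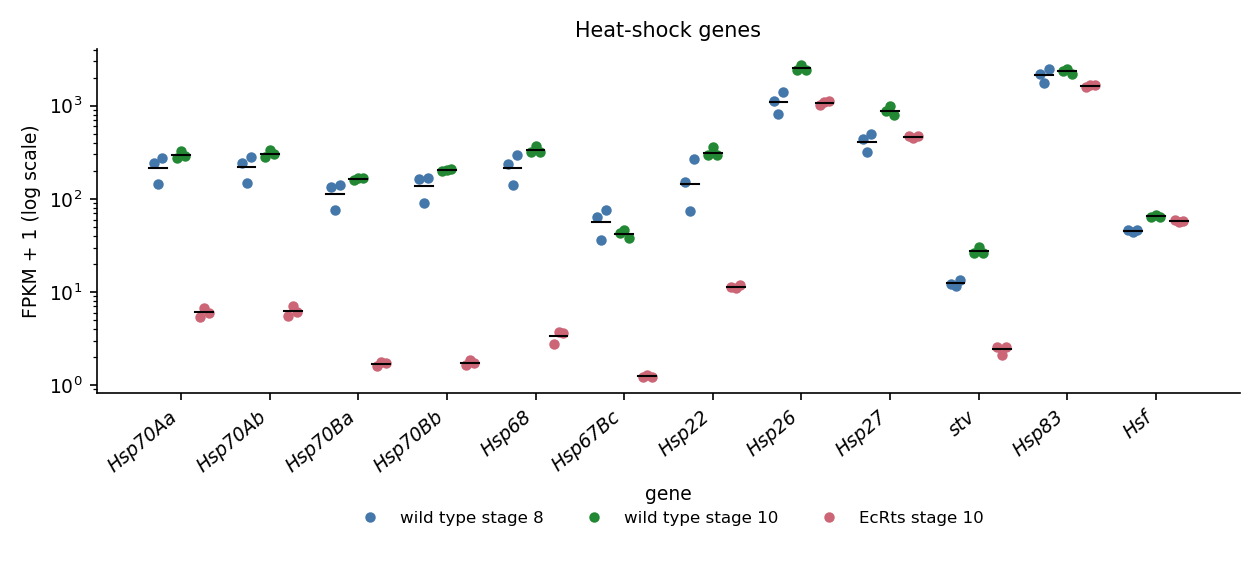
FPKM + 1 (y axis, log scale) of 12 heat shock genes in the 3 groups; dots are libraries and bars are the means of log2(FPKM + 1) of a group. Hsp70 copies, Hsp68 and Hsp67Bc lie near the floor in all 3 EcRts libraries, with Hsp70Bb at 0.731 FPKM against 203 in wild-type stage 10 and 140.0 at stage 8.

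Among the largest rises in EcRts, the uncharacterised gene CG4476 (FBgn0035969, chromosome 3L, 9204980 to 9208356) was at 50.1 ± 2.05 FPKM against 2.49 ± 0.463 in wild type, a log2 change of 3.88 (adjusted p = 8.14e-06). Oat (FBgn0022774, chromosome 3L, 19640380 to 19642951), the ornithine aminotransferase gene, was at 21.5 ± 2.03 against 1.90 ± 0.347 (2.96, adjusted p = 2.86e-06). CG6891 was at 32.4 ± 2.66 against 4.53 ± 0.363, the cytochrome P450 gene Cyp6a22 at 31.5 ± 3.75 against 8.01 ± 0.773, and Arc1, a capsid-like gene, at 24.3 ± 13.2 against 3.05 ± 0.191. CG11034, Obp46a, CG6900 and CG42565 rose by 2.08 to 2.84 on the log2 scale. The mitochondrial transfer RNA mt:tRNA:C, a small RNA that was ranked because the symbol pattern for small RNAs does not match it, was listed at 0 in all wild-type stage 10 libraries and in 1 stage 8 library, and had 371 ± 207 FPKM in EcRts. CG42704 was listed at 0 in EcRts and had 103 ± 114 in wild-type stage 10, and its call (adjusted p = 0.0259) was lost without EcRts replicate 1 (adjusted p = 0.0613), replicate 2 (0.0617) or replicate 3 (0.0614) and with robust variance (0.0545), with a range of 1.03e-04 to 0.0617 over the alternatives.

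Most chorion genes and few vitelline membrane genes were lower in EcRts. Of 11 chorion genes 8 were lower and 0 higher (median −1.52), and 7 or 8 were lower under each scaling. The list did not pass camera with the values as deposited (adjusted p = 0.0751), and was not called without eggshell and yolk genes either (0.447). It passed with median-of-ratios (0.0101), quantile (0.00633) and protein-coding scaling (4.19e-04), with only the 2 groups compared (0.0109), with no filter (0.00482), without stage 8 replicate 1 (0.0106) and without EcRts replicate 2 (0.0316), with a range of 4.19e-04 to 0.802 over the alternatives. Cp7Fc fell from 1041 ± 76.2 to 314 ± 89.5 FPKM (−1.76, adjusted p = 0.00136), Cp7Fb from 448 ± 29.1 to 160.1 ± 38.4, Cp38 from 4624 ± 446 to 1586 ± 554 and Cp36 from 3206 ± 414 to 1268 ± 329. Of 13 vitelline membrane genes 1 was lower in EcRts, or 0 adjusted over the list alone (median −0.09, camera higher, adjusted p = 0.709), a median that turned to 0.04 with median-of-ratios and 0.11 with protein-coding scaling, both with 0 lower, while 3 were lower with quantile normalization and 4 without eggshell and yolk genes. That gene, named after its values were seen, was Vm32E, at 2512 ± 289.6 against 4324 ± 294 (adjusted p = 0.0372), while Vm26Ac had 247 ± 61.2 against 272 ± 13.5 (adjusted p = 0.639). Among 8 yolk and lipoprotein uptake genes 1 was higher, or 0 adjusted over the list alone (median 0.01, camera adjusted p = 0.336), and 3 were lower without eggshell and yolk genes.

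Lists of sugar, lipid and energy metabolism did not pass camera with the values as deposited. Of 11 glycogen and trehalose genes 7 were lower and 1 higher under the values as deposited (median −0.27, camera adjusted p = 0.0556). Camera passed without wild-type stage 10 replicate 1 (adjusted p = 0.0338) or replicate 3 (0.0395), without EcRts replicate 1 (0.0402) and with no filter (0.00372), with a range of 0.00372 to 0.802 over the alternatives with camera, and 4.3e-04 with fry. Under the scalings 4 to 9 genes of this list were lower and 0 to 2 higher. Treh fell from 74.5 ± 4.80 to 37.5 ± 1.04 FPKM (−0.97, adjusted p = 1.36e-05), the trehalose transporter gene Tret1-1 from 15.9 ± 3.68 to 5.60 ± 0.763, and Pgm from 97.2 ± 3.07 to 71.4 ± 0.788. Of 12 glycolysis genes 9 were lower and 1 higher (median −0.31, camera adjusted p = 0.0574). The glycolysis list passed with median-of-ratios scaling (adjusted p = 0.0498), with no filter (0.00482) and without wild-type stage 10 replicate 3 (0.0395), but not with quantile normalization (0.184), in a range of 0.00482 to 0.802 over the alternatives with camera, and 0.00121 with fry. Under the scalings 5 to 10 of its genes were lower and 0 to 2 higher. Hex-A fell from 78.2 ± 3.58 to 57.9 ± 0.547. In lipid synthesis 13 of 25 genes were lower and 4 higher, and 8 and 8 with protein-coding scaling (median −0.23, camera adjusted p = 0.343). AcCoAS, the acetyl-CoA synthetase gene, fell from 47.1 ± 1.96 to 14.5 ± 0.565 (−1.63, adjusted p = 1.32e-06). Of 18 lipolysis and beta-oxidation genes 10 were lower and 2 higher, which turned to 4 and 6 with protein-coding scaling (median −0.29, camera adjusted p = 0.336), and the triglyceride lipase gene bmm fell from 38.2 ± 2.32 to 21.6 ± 0.817. Counts of these 4 lists were the same adjusted over the list alone. Nuclear oxidative phosphorylation genes had 6 of 42 lower, or 5 adjusted over the list alone (median −0.07, camera higher, adjusted p = 0.693), and protein-coding scaling turned this to 21 higher and 0 lower. That list passed camera as higher with quantile normalization (adjusted p = 0.00633) and protein-coding scaling (0.0202), with a range of 0.00633 to 0.994 over the alternatives. Of 15 TCA cycle genes 5 were lower and 1 higher, both over all genes and adjusted over the list alone (median −0.02, camera adjusted p = 0.98), turning to 2 lower and 7 higher with protein-coding scaling. Idh fell from 249.7 ± 13.5 to 175 ± 2.04 and kdn rose from 107 ± 11.3 to 146 ± 6.87.

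The ecdysone response list did not move as a set. Of its 20 genes 4 were higher and 6 lower in EcRts, both over all genes and adjusted over the list alone (median 0.01, mean −0.09, camera higher, adjusted p = 0.448), turning to 9 higher and 3 lower with protein-coding scaling. Eip74EF fell from 11.2 ± 0.823 to 4.97 ± 0.279 FPKM (−1.03, adjusted p = 1.13e-04), the insulin-binding protein gene ImpL2 from 86.4 ± 9.98 to 43.7 ± 2.87 and Eip93F from 2.52 ± 0.349 to 0.925 ± 0.14, while the nuclear receptor gene Hr4 rose from 2.13 ± 0.244 to 4.51 ± 0.486. Of 13 ecdysteroid synthesis genes 6 were lower and 2 higher, also when adjusted over the list alone (median −0.18, 0.01 with protein-coding scaling, camera adjusted p = 0.98). Start1 fell by 0.42 on the log2 scale and CG4688, now called GstE14, from 3.71 ± 0.404 to 1.28 ± 0.212, while sad rose from 4.94 ± 0.495 to 6.99 ± 0.304.

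Counts of cell cycle genes also depended on the scaling. Of 23 DNA replication and endocycle genes 16 were lower and 0 higher (18 lower adjusted over the list alone; median −0.27, camera adjusted p = 0.00341, and 0.802 with an estimated correlation). Under median-of-ratios scaling 11 were lower, under quantile normalization 10 and without eggshell and yolk genes 22. With protein-coding scaling 5 were lower and 2 higher and the camera call was lost (adjusted p = 0.0768; 1.1e-05 to 0.802 over the alternatives). RnrL fell from 159.7 ± 2.80 to 104 ± 6.73 FPKM, RnrS from 196 ± 6.23 to 145 ± 5.35 and Orc2 from 25.4 ± 0.91 to 16.4 ± 1.40. Of 17 mitotic cycle genes 10 were lower, also when adjusted over the list alone, and 5 were lower and 4 higher with protein-coding scaling (median −0.23, camera adjusted p = 0.167, and 0.0182 with no filter, in a range of 0.0182 to 0.802 over the alternatives with camera, and 0.00318 with fry), with mad2 from 108 ± 8.25 to 71.0 ± 4.15 and the checkpoint kinase gene BubR1 from 25.0 ± 0.997 to 16.2 ± 1.74. Of 14 actin and dumping genes 9 were lower and 0 higher, the same adjusted over the list alone (median −0.22, camera adjusted p = 0.203, and 0.027 with no filter, in a range of 0.027 to 0.802 over the alternatives with camera, and 0.00162 with fry), turning to 1 lower and 3 higher with protein-coding scaling. The filamin gene cher fell from 38.1 ± 1.20 to 28.5 ± 1.78. Among 18 follicle cell patterning genes 6 were lower and 2 higher (7 and 3 adjusted over the list alone; median −0.13, camera adjusted p = 0.98), and 4 and 5 with protein-coding scaling. Fas3 fell from 18.9 ± 1.48 to 10.2 ± 0.963, the transcription factor gene ct from 2.90 ± 0.266 to 1.19 ± 0.141 and aos, an inhibitor of EGF receptor signalling, from 2.99 ± 0.212 to 1.27 ± 0.26. Maternal patterning and germline genes were 6 lower and 3 higher of 21, the same adjusted over the list alone (median −0.02, camera higher, adjusted p = 0.336), turning to 0 lower and 8 higher with median-of-ratios scaling, and fs(1)K10 rose from 17.5 ± 1.24 to 25.6 ± 1.26. Of 4 germarium genes 2 were higher and 1 lower, the same adjusted over the list alone (median 0.09, camera adjusted p = 0.343), turning to 0 and 1 without eggshell and yolk genes.

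Counts of ribosomal protein and proteasome genes depended on the scaling. Of 88 ribosomal protein genes 31 were lower and 1 higher (30 and 1 adjusted over the list alone; median −0.10, camera adjusted p = 0.336), turning to 2 lower and 5 higher with median-of-ratios scaling (median 0.02) and 2 lower and 32 higher with protein-coding scaling. This list passed camera as lower without wild-type stage 10 replicate 2 (adjusted p = 0.0468), with quantile normalization (0.00299), without eggshell and yolk genes (0.00316) and with array weights (0.0378), with a range of 0.00299 to 0.962 over the alternatives. RpS15Ab fell from 449 ± 23.8 to 349 ± 15.5 FPKM. Of 30 proteasome genes 14 were lower, or 21 adjusted over the list alone (median −0.21, camera adjusted p = 0.0276, and 0.913 with an estimated correlation). The number lower was 3 under median-of-ratios scaling, 4 under quantile normalization, 30 without eggshell and yolk genes and 0 with protein-coding scaling. The camera call for the proteasome was lost without wild-type stage 10 replicate 1 (adjusted p = 0.0594), EcRts replicate 1 (0.0683) or EcRts replicate 3 (0.0721), with a mean of at least 5 FPKM (0.0691), and with quantile (0.305) or protein-coding scaling (0.195), with a range of 6.13e-04 to 0.913 over the alternatives.

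In growth and stress signalling, Thor fell further, from 71.8 ± 7.18 to 23.7 ± 5.09 FPKM (−1.58, adjusted p = 3.24e-04). Of 16 insulin and TOR genes 8 were lower and 1 higher (median −0.14, 0.06 with protein-coding scaling, camera adjusted p = 0.647), and chico, an insulin receptor substrate gene, fell from 14.4 ± 0.688 to 10.4 ± 0.279. Of 19 apoptosis and autophagy genes 13 were lower and 1 higher (13 and 2 adjusted over the list alone; median −0.37, camera adjusted p = 0.167, and 0.042 with no filter, in a range of 0.042 to 0.802 over the alternatives with camera, and 4.3e-04 with fry). Under median-of-ratios scaling 8 were lower and 3 higher, under quantile normalization 9 and 3, and with protein-coding scaling 6 and 4. Nc fell from 43.7 ± 1.38 to 33.1 ± 0.734, the cell death gene W (hid) from 10.6 ± 0.43 to 7.08 ± 0.482 and rpr from 1.03 ± 0.174 to 0.0963 ± 0.0636. Among 19 xenobiotic and oxidative stress genes 7 were lower and 2 higher (median −0.15, camera adjusted p = 0.709), turning to 3 and 5 with protein-coding scaling. Cyp6w1 fell from 7.85 ± 2.12 to 0.914 ± 0.754 and GstD2 from 8.66 ± 2.18 to 2.00 ± 1.05, while GstS1 rose from 49.8 ± 1.17 to 70.7 ± 3.98. Of 7 immune peptide genes 2 were higher and 2 lower (3 and 2 adjusted over the list alone; median 0.77, camera adjusted p = 0.203). The immune list passed without wild-type stage 10 replicate 3 (adjusted p = 0.0472), without eggshell and yolk genes (0.0111) and with no filter (0.00634), in a range of 0.00634 to 0.941 over the alternatives. Relative to all tested genes the mean change of the immune list was 0.84, and it ran from 0.46 without EcRts replicate 1 to 1.54 without wild-type stage 10 replicate 1. CecA1 was at 4.22 ± 3.34 in EcRts and 0.104 ± 0.18 in wild type. Of 10 muscle genes 4 were higher and 1 lower (median 0.62, camera adjusted p = 0.00979, and 0.802 with an estimated correlation). Camera no longer passed for muscle with median-of-ratios (adjusted p = 0.052), quantile (0.0501) or protein-coding scaling (0.105), with a range of 1.4e-04 to 0.802 over the alternatives. Levels were low, as for Tm2 (1.77 ± 0.285), Mlc1 (1.53 ± 0.377) and Mlc2 (1.66 ± 0.177), and all 3 calls were lost without wild-type stage 10 replicate 2 (adjusted p = 0.0503, 0.0558 and 0.0504). The call of Tm2 was also lost without EcRts replicate 2 (0.0534), and that of Mlc2 without wild-type stage 10 replicate 1 (0.0538) or EcRts replicate 1 (0.0573). Among 5 fat body genes 1 was higher and 1 lower (median −0.32, camera higher, adjusted p = 0.866). Insulin, xenobiotic, muscle and fat body counts were the same adjusted over the list alone.

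**Figure D4:**
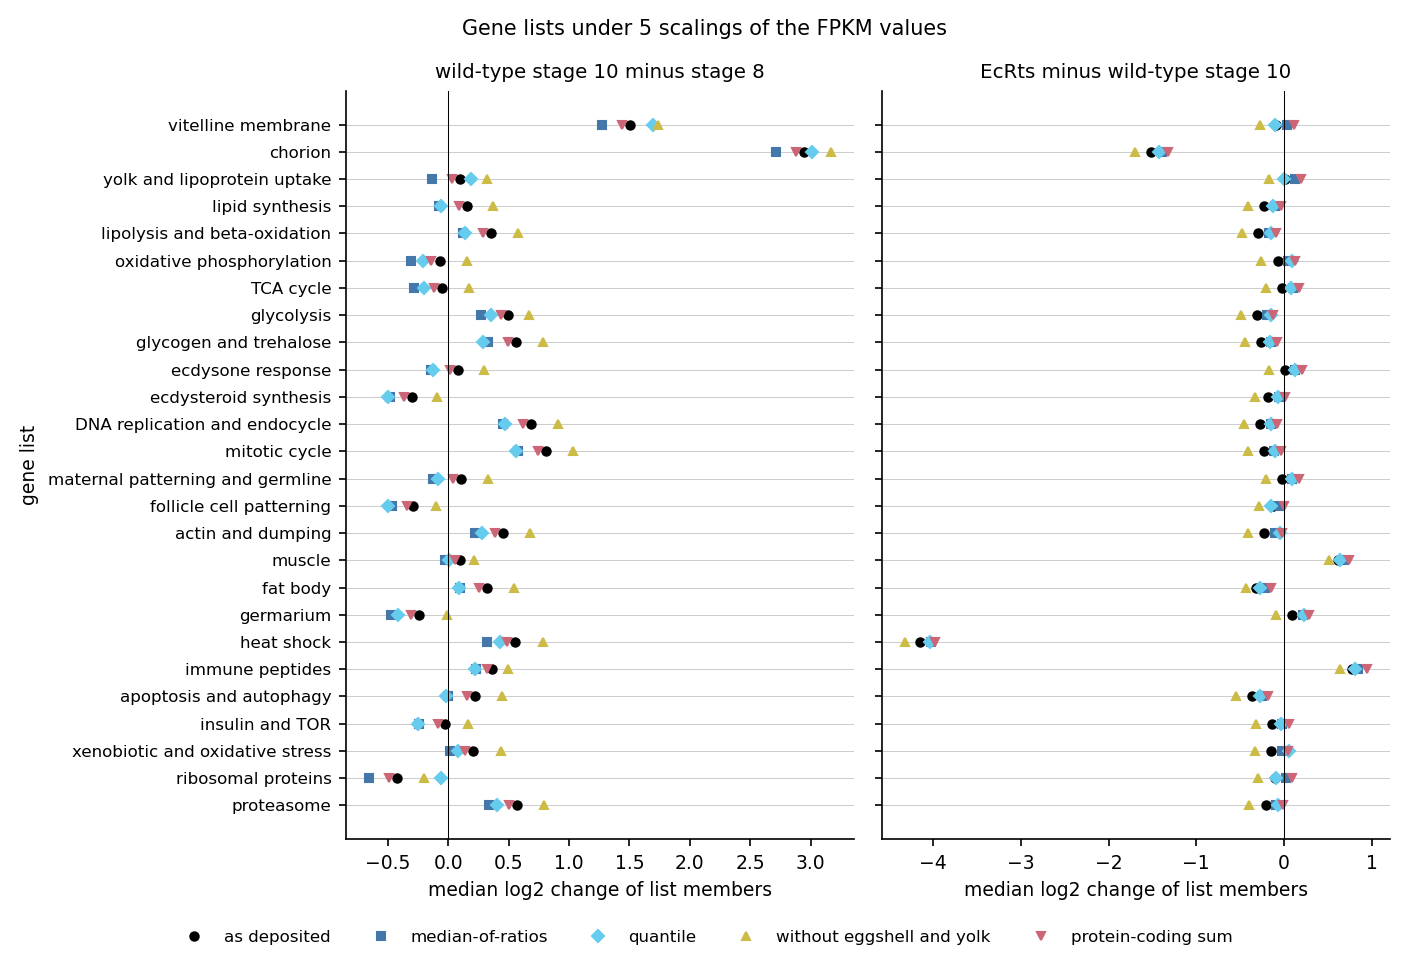
Median log2 change (x axis) of the members of 26 gene lists under the values as deposited and 4 scalings, for wild-type stage 10 against stage 8 and for EcRts against wild-type stage 10. Chorion and proteasome lie above 0 in the stage comparison and heat shock and chorion below 0 in the EcRts comparison under all 5, while oxidative phosphorylation, TCA cycle and maternal patterning medians change sign with the scaling in both.

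EcRts stage 10 was also compared with wild-type stage 8, which asks how far the mutant follicles lie from the earlier stage. Of the 8340 genes 5117 passed, 3320 higher and 1797 lower in EcRts (64.9% higher, and 50.6% to 76.4% under the scalings). Chorion genes were higher than at stage 8 in 10 of 11 cases (median 1.55, camera adjusted p = 0.0438, and 0.568 with an estimated correlation), and vitelline membrane genes in 10 of 13 with 3 lower (median 1.53, camera adjusted p = 0.254). Mitotic cycle genes were higher in 16 of 17 cases (median 0.60, camera adjusted p = 3.54e-05, and 0.554 with an estimated correlation) and proteasome genes in 29 of 30 (median 0.38, camera adjusted p = 8.22e-05, and 0.673 with an estimated correlation). Ribosomal protein genes were lower in 86 of 88 cases (median −0.55, camera adjusted p = 2.35e-31, and 0.554 with an estimated correlation). Heat shock genes were lower than even at stage 8 in 14 of 18 cases and higher in 1 (median −3.01, camera adjusted p = 4.22e-08, and 0.568 with an estimated correlation). The medians of these 6 lists kept their sign under every scaling, and their counts were the same adjusted over the list alone. With the values as deposited camera called 11 lists here, and 0 with an estimated correlation. Called too were DNA replication and actin (higher) and ecdysteroid synthesis (lower). So were follicle cell patterning (11 of 18 lower, 2 higher), oxidative phosphorylation (15 of 42 lower, 1 higher) and TCA cycle (9 of 15 lower, 0 higher). Of 10 muscle genes 8 were higher and 1 lower (median 0.76, camera adjusted p = 0.132).

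Many genes moved one way with stage and the other way in EcRts. Of the genes that rose with stage 2138 were lower in EcRts, where 1391 would overlap if the sets of genes were independent, and of those that fell 366 were higher, against 157. Another 121 genes rose and were higher, and 207 fell and were lower. Both comparisons share the 3 wild-type stage 10 libraries, which alone produces opposite signs, and these libraries were not split between the comparisons. Across genes, which are not independent replicates, the 2 sets of changes correlated at −0.509, and 100 simulations with noise only gave −0.502 ± 0.0503 (SD). Their covariance was −0.26, against −0.05 ± 0.00772 in the simulations, and signs were opposite for 72.3% of genes, against 66.6% ± 0.529 with noise only. The simulations hold no difference between groups, and 3 groups that differ independently would lower the covariance too. The covariance therefore does not decide whether the changes oppose each other beyond the shared libraries. Under the scalings the share of opposite signs was 62.0%, under the noise-only share, to 80.4%, and the correlation −0.527 to −0.495. The genes pim, Orc2, RnrL, Eip74EF, Fas3, Treh and the chorion genes Cp7Fb and Cp38 rose with stage and were lower in EcRts, and sad, kdn and fs(1)K10 fell with stage and were higher. The lipid droplet gene Lsd-2 (EcRts change 0.03, adjusted p = 0.748) and nos (0.01, adjusted p = 0.95) rose with stage. With the values as deposited neither was called between EcRts and wild type. Both lie outside the naming rule for the EcRts comparison, and their EcRts changes under the scalings are not given here.

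**Figure D5:**
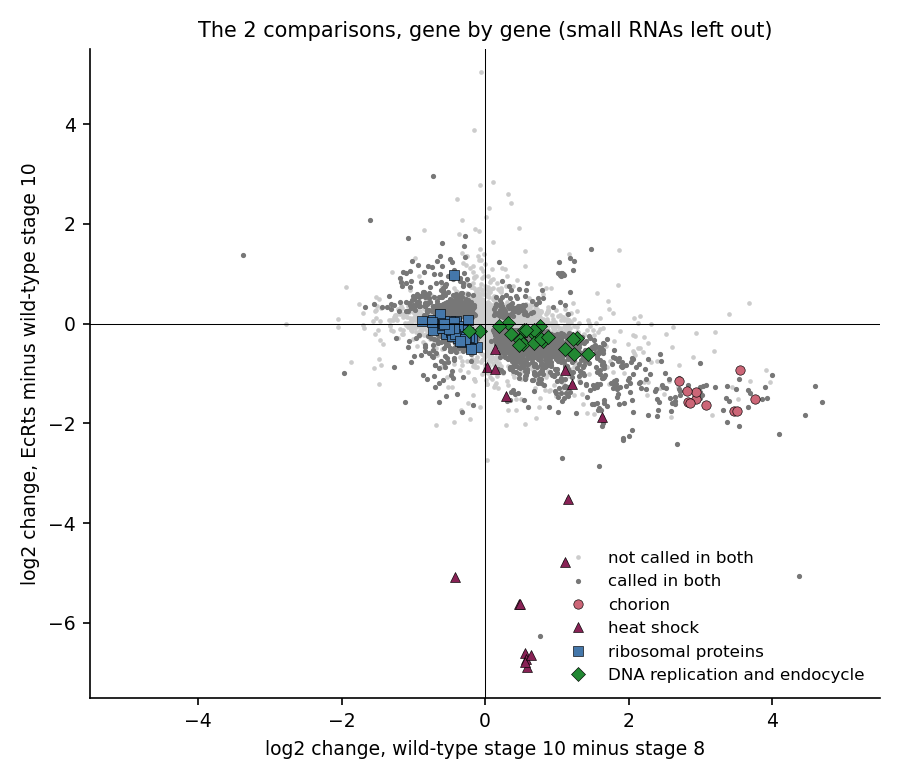
Log2 change from wild-type stage 8 to stage 10 (x axis) against log2 change from wild-type stage 10 to EcRts (y axis) for 7757 genes, 2 of them outside the axes. Genes that match the symbol pattern for small RNAs and pseudogenes, which takes in all symbols starting with CR, are left out. Each dot is a gene, and chorion, heat shock, ribosomal protein and DNA replication genes are marked. Chorion and DNA replication genes that rose with stage lie mostly below 0 on the y axis, and all 18 heat shock genes lie below it, from far below for the Hsp70 copies to −0.17.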

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

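The protein-coding scaling was chosen after seeing the data, and all other alternatives were planned. For the 141 named-gene results, 3175 of 3200 values under the alternatives kept their direction and their side of the threshold, 22 fell short of it, 2 passed it and 1 reversed. For the 52 list results these were 1211 of 1296, 30, 53 and 2. List members were preferred for naming when their call held under these same alternatives. The share for named genes is therefore partly fixed by that choice and does not measure how stable gene calls are in general. Scaling changed the balance of directions. Median-of-ratios scaling gave 2596 genes higher and 2669 lower with stage and 1644 higher and 1571 lower in EcRts, and quantile normalization gave 2626, 2537, 1596 and 1744 in the same order. Scaling without eggshell and yolk genes gave 868 lower with stage, 456 higher and 5180 lower in EcRts, and 4335 genes called in both comparisons with opposite signs. With protein-coding scaling 2249 genes were higher and 1052 lower in EcRts and 496 genes had the same sign in both comparisons. The protein-coding sum leaves out the noncoding transcripts of unplaced scaffolds, and the sum without eggshell and yolk genes keeps them. These transcripts took 29.0% of the summed FPKM in EcRts and 10.0% in wild-type stage 10. Which scaling is closest to the true levels was not settled. Array weights gave 548 genes with the same sign, and the cause was not tested. Requiring a change of at least 2-fold left 598 higher and 194 lower with stage and 229 higher and 246 lower in EcRts, by construction. The lists called in EcRts went from 4 to 11 with no filter and to 2 with a mean of at least 5 FPKM, and the cause was not tested. With a correlation estimated per list camera called 0 lists in the stage comparison and 0 in EcRts (0 and 0 at an unadjusted p under 0.05), while fry, which tests whether members move one way and not against other genes, gave 18 and 16.

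3 results reversed. EcR fell with stage under quantile normalization (−0.1717, adjusted p = 0.00916) and rose without eggshell and yolk genes (0.3235, adjusted p = 0.00115), in a range of 0.00115 to 0.605 over the alternatives. With fry in place of camera the ecdysone response list (0.129) and the muscle list (0.212) moved up with stage, as their means do, while camera set them below the other genes; fry makes no such comparison.

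Leaving out 1 library at a time gave 3779 to 4074 genes higher and 1333 to 1565 lower with stage, 560 to 821 higher and 2186 to 2887 lower in EcRts, and 2852 to 3325 higher and 1545 to 1802 lower in EcRts against stage 8. Lists called were 9 to 10 with stage and 3 (without EcRts replicate 3) to 7 (without wild-type stage 10 replicate 3) in EcRts. Genes called in both comparisons were 1955 to 2451 with opposite signs and 198 (without wild-type stage 10 replicate 1) to 310 with the same sign. The cause was not tested. The labels do not say whether equal replicate numbers pair the samples. Deviations of libraries with the same number correlated at −0.0389 to 0.2301 and those with different numbers at −0.2345 to 0.1667, so pairing was not settled. With a block for the replicate number 4029 genes were higher and 1521 lower with stage, 748 higher and 2588 lower in EcRts, 2271 had opposite signs and 264 the same sign. At this depth, genes near 1 FPKM carry the least precise values.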

Other observations

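The tests below were chosen after the results they measure had been seen, and the families of this and the next paragraph were defined after their values were seen. Of the 13 protein-coding messenger RNAs of the mitochondrial genome 10 rose with stage and 0 fell (median log2 change 1.02, camera adjusted p = 0.0841, and 0.604 with an estimated correlation), and 7 to 12 rose under the scalings. Camera passed with median-of-ratios (adjusted p = 0.0133), quantile (0.00288) and protein-coding scaling (0.0457), but not without eggshell and yolk genes (0.251). In EcRts all 13 were lower than in wild-type stage 10 (median −1.27, camera adjusted p = 6.63e-04, and 0.54 with an estimated correlation), and 9 to 13 were lower under the scalings. Without wild-type stage 10 replicate 3, whose share of these transcripts was 3.70%, 9 rose with stage (median 0.68) and 13 were lower in EcRts (median −0.90), and the number lower in EcRts went to 7 without EcRts replicate 1 and to 8 without EcRts replicate 2. Nuclear oxidative phosphorylation genes had median changes of −0.07 in both comparisons, with directions that turned to 21 higher and 0 lower without eggshell and yolk genes (stage) and with protein-coding scaling (EcRts).

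The tested copies of replication-dependent histone genes were of the types His1, His2A, His2B and His4. They share reads within a type, so their counts are not independent. All rose with stage, 88 of 88 under every scaling (median 1.11, camera adjusted p = 1.41e-12, and 0.368 with an estimated correlation). In EcRts the types parted: 20 of 20 His2A copies were lower than in wild-type stage 10 (median −0.50), 23 of 23 His2B copies were higher (median 0.99), and 0 of 23 His1 and 0 of 22 His4 copies differed. Median levels in wild-type stage 10 and EcRts were 68.6 and 48.3 FPKM for His2A. They were low for the other types, at 3.13 and 7.24 for His2B, 4.14 and 4.45 for His1, and 3.22 and 4.05 for His4. The 98 copies of 5S rRNA were at a median change of −0.27 with stage, where 4 fell, and 94 of them were higher in EcRts (median 1.84, camera adjusted p = 1.53e-38, and 0.411 with an estimated correlation), with 94 to 95 higher under the scalings. Of 7 host genes of small nucleolar RNAs 6 fell with stage under every scaling (median −1.34, camera adjusted p = 1.43e-05, and 0.222 with an estimated correlation), and in EcRts 1 was lower and 0 higher, which turned to 2 higher and 0 lower with median-of-ratios scaling and quantile normalization and 3 higher and 0 lower with protein-coding scaling. Of 214 small nucleolar RNAs 51 fell and 4 rose with stage (median −1.13, camera adjusted p = 2.84e-11, and 0.0411 with an estimated correlation), with 39 to 56 falling under the scalings. In EcRts 30 of them were higher and 5 lower (median 1.02, camera adjusted p = 2.31e-12, and 0.0323 with an estimated correlation), with 31 to 37 higher under the scalings and camera at 0.142 with protein-coding scaling. Under the scalings the calls with an estimated correlation held only without eggshell and yolk genes (adjusted p = 0.00501 with stage and 0.00206 in EcRts), at 0.0974 to 0.295 and 0.387 to 0.7 under the other scalings. Histone, 5S and small nucleolar transcripts mostly lack poly(A) tails, so their values in poly(A)-selected libraries also depend on how selective that step was, which was not tested. These are 5 of 11 families examined, and the other 6 were mitochondrial ribosomal proteins, nucleoporins, the vacuolar ATPase, glutathione transferases, cytochrome P450s and translation initiation factors. For these camera with an estimated correlation gave adjusted p = 0.333 to 0.985 over both comparisons. With the preset correlation it called the vacuolar ATPase with stage (adjusted p = 3.16e-04; 2 rose and 9 fell, turning to 9 and 4 without eggshell and yolk genes), the initiation factors with stage (4.52e-05; 4 rose and 14 fell, turning to 9 and 6 under that scaling) and the nucleoporins in EcRts (0.0245; 11 lower and 0 higher, and 2 each with protein-coding scaling).

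The 18 heat shock genes were lower in EcRts by a median of −4.15 on the log2 scale, the 6 Hsp70 copies by −6.66 and the 12 others by −1.34. Library scaling does not account for it, since the median of the list stayed at −3.979 or lower and that of the 12 others at −1.14 or lower under every scaling. Reads shared between Hsp70 copies do not either, because the copies summed to at most 14.9653 FPKM in an EcRts library and at least 1274 in a wild-type stage 10 library. With the values as deposited all 12 other members were lower as well. Handling that goes with the group cannot be told apart from genotype and temperature, as each group was 1 genotype at 1 temperature, and 14 of the 18 members were lower in EcRts than in wild-type stage 8 too. A lower level in EcRts may then come from the mutation, from acclimation to the other temperature, or from heat shock induced in the wild-type samples.

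Genes that rose with stage tended to be lower in EcRts, with a covariance of −0.260738 where noise of the shared wild-type stage 10 libraries gives −0.05 ± 0.00772 in the simulations. The simulations hold no difference between groups, and 3 groups that differ independently would lower the covariance too. Signs were opposite for 72.3% of genes against a simulated 66.6% ± 0.529. Under the scalings this share went from 62.0%, under the simulated one, to 80.4%. The correlation of −0.508854 lies within the simulated −0.502 ± 0.0503, as it would for any 3 groups that differ independently, so opposition beyond the shared group is not settled and a shift common to the 3 wild-type stage 10 libraries cannot be told apart from a difference in stage and genotype. Stage 8 follicles mixed into the EcRts samples would pull all genes to the same position between the 2 wild-type groups. The chorion genes that rose lay at a median of 0.29 of the way from stage 8 to stage 10 (range 0.207 to 0.476). The vitelline membrane genes that rose lay at 0.874 (range 0.343 to 1.32, permutation p = 0.00073 with 100000 resamples of genes). The resampling treats co-regulated genes as independent, and the 2 lists were picked after their difference had been seen. Its p therefore does not measure the spread between samples. At most, these positions argue against a mixture with no other difference between EcRts and wild type. EcRts follicles collected earlier within stage 10 cannot be told apart from a delay caused by the mutation or the temperature, since 8 chorion genes, which come on late, were lower and no label gives the position within the stage.

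The balance of higher and lower calls depends on the scaling, and transcripts of unplaced scaffolds took 29.0% of the summed FPKM in EcRts and 10.0% in wild-type stage 10, and of 53 such genes tested 33 were higher and 9 lower in EcRts (median 1.29). After protein-coding scaling 31.9% of the EcRts calls were lower, against 2826 of 3654 with the values as deposited, but 1 factor per library turns the balance whatever caused the shift. Within groups the level of the typical gene and this share correlated at −0.141 (one-sided permutation p = 0.366), and 9 libraries are too few to decide, so this cause cannot be told apart from any other shift common to the genes of a library. The identity of these transcripts was not settled, and they may include ribosomal RNA left after poly(A) selection, as 6 of the 94 carry such symbols. In the stage comparison 66.2% of calls were still higher after protein-coding scaling, so there these transcripts are not the whole cause.

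With 3 libraries per group only 10 splits of 6 libraries exist, too few for a share under 0.05. The real split gave 5682 genes in the stage comparison, as many as 1 of 10 splits (itself), with at most 4 genes in another split. For EcRts against wild-type stage 10 it gave 3654 genes (1 of 10 splits, at most 2 elsewhere), and for EcRts against stage 8 it gave 5117 (1 of 10, at most 15 elsewhere). Gene lists were less distinct: 3 of 10 splits gave as many as the 9 lists of the stage comparison, with 9 in another split, and 6 of 10 gave as many as the 4 lists of the EcRts comparison, with 8 in another split. Of 100 regroupings of all 9 libraries 2 gave as many genes called in both comparisons with opposite signs as the real 2504, the real grouping among them. Mixing groups that differ widens the spread within a group, so low counts elsewhere follow from any difference between the groups. This share therefore does not exclude chance for that count. Most regroupings mix the groups and 90 of them gave at most 1 gene, so the count shows that the groups differ and not that the changes oppose each other beyond the shared group. The other regrouping with as many, with 3307 genes, compared both mixed stage 10 groups with the 3 stage 8 libraries as the shared group, which points to the stage structure of the samples.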
